A study of Oryza sativa with 10 samples.

How the data were processed

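G-quadruplex capture was measured in rice seedlings with 3 capture groups of 2 libraries each and 4 control libraries, 10 libraries in 7 groups. Per the labels' protocols, 2-week-old seedlings were fixed with 1% formaldehyde for 10 min, and captured DNA was sequenced in paired-end mode. Per the labels, the capture groups had biological replicates. The submitters' processing notes name Trim Galore 0.4.4, BWA, Picard, SAMtools 1.5 and MACS2 2.1.1, without the role or order of each. The genome build, the control library behind each list, the q threshold and the pooling of replicates are not given in the sources used here.

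The deposited files are 4 peak lists of 10 columns with no header, 1 per capture, in the column order that MACS2 gives to narrow peaks. The deposited score of a peak was the whole part of its −log10 q times a constant in 100% of rows of the in vitro lists and 99.99% of BioTASQ in vivo rows. The deposited fold enrichment is the ratio of the peak to its control, as the authors' peak caller gave it. The deposited −log10 p and −log10 q values come from the same caller, and no p or q was recomputed. Fold, score and −log10 q were used to describe, rank or filter peaks within a list. Fold enrichment was also correlated between overlapping peaks of different lists by rank, and solved together with −log10 p for the control level. In the BioTASQ in vivo list 13208 rows (22.97%) had a summit beyond the end of the row, against 1004 (2.01%) for BioCyTASQ in vitro and 0 for the BG4/BioTASQ in vitro list, so rows of the first 2 lists had been cut after calling. The numbers in the peak names covered 65.0%, 95.1% and 99.4% of the numbers up to the highest, in the same order, so peaks had also been removed from the lists by steps not given in the sources used here.

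Each list was read with its 12 nuclear chromosomes, and 26 repeated rows of the BG4/BioTASQ in vitro list were dropped. The BG4 and BioTASQ in vitro lists were compared row by row and held the same rows, so their planned overlap test was not run and they were used once. A peak was counted as shared where it overlapped a peak of the other list by at least 1 bp. Chance placement came from 100 shuffles of the first list within each chromosome, whose length was taken as the largest peak end of any list (373 Mb in all). The observed minus the shuffled share was tested over the 12 chromosomes with an exact two-sided sign-flip permutation test of 4096 sign assignments, at a threshold of 0.05. Chromosomes are spatial units and not replicates. Adjustment was by Benjamini-Hochberg within each family. For trends, peaks of a list were put in 5 groups of equal size by fold enrichment, and the overlap of the strongest minus that of the weakest group was tested in the same way.

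For the control level, fold enrichment and −log10 p of each peak were solved for the pileup, the number of fragments at the summit, and for the level that the caller expected there from the control, under the Poisson formulas of MACS2. Whole pileups came out for 100% of BioCyTASQ in vitro and BioTASQ in vivo peaks, within 0.001 on the −log10 p scale. Only 0.333% of BG4/BioTASQ in vitro peaks gave a whole pileup, so levels in that list are approximate. The lowest level, which tracks depth, was 8.14 fragments for BioCyTASQ and 15.7 for BioTASQ in vivo, and the median pileup 61 and 76. These are the only measures of depth used here, and they belong to lists and not to single libraries.

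The steps were tested on simulated data. With 49898 intervals placed at random, the overlap step returned a share placed on peaks of −0.063% (p = 0.707, exact sign-flip permutation test), and with 30% placed on peaks it returned 29.9%. The 3 overlap rules gave the known answers. For 5000 simulated whole pileups, 100% of control levels came back within 1%, and for 5000 scaled pileups 99.2% came back within 20%. The simulated levels were mostly higher than those of the BG4/BioTASQ in vitro list, whose median was 3.81 fragments. In that list 312 peaks (1.06%) came out at 0.001 fragments, the lower limit of the solution. The 20% therefore need not hold for it. Python 3.11.15 was used with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9.

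The overlaps of BioCyTASQ in vitro and of BioTASQ in vivo with the BioTASQ in vitro list, the overlap of all lists, their alternatives and the rule for named regions were fixed before the data were examined. The rule for regions was to name the 3 strongest shared peaks of a comparison and the 3 strongest peaks of each list only, by fold enrichment, at most 1 per 100 kb. For shared regions the strength was the mean of the ranks of both peaks, each divided by the length of its list. The comparison of BioCyTASQ in vitro with BioTASQ in vivo, the ratios between overlaps, trends with strength, pileup and control level, shifts, 1 Mb densities and chromosome ends were chosen after the data were examined. Alternatives were overlap of 50% of the shorter peak, 50% reciprocal overlap, the stronger peaks of each list alone, equal numbers of the strongest peaks (29443), windows of 200 bp at the summit (at the centre of rows whose summit lies beyond the row end), shuffling within 1 Mb blocks, merging peaks within 100 bp and leaving out each chromosome. Those added later were a −log10 q of at least 3 in every list, joining the pieces of a called peak, ranking by −log10 q, 200 bp windows at the centre of every row and an outer zone of 3 Mb. The alternatives of results chosen later were likewise applied later.

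Planned counts of G-quadruplex motifs, base composition, gene annotation, gene lists and named genes were not run, because no genome or annotation of the build was used here. Biotin and input libraries were not analysed here other than through the fold enrichments. Per-replicate values were not analysed here.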

Results

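The series set the antibody BG4 against small-molecule baits for the capture of G-quadruplex DNA, the stacked structures that guanine-rich strands can fold into. The baits were BioTASQ and BioCyTASQ, biotin-carrying members of the TASQ family (template-assembled synthetic G-quartets), which were pulled down with streptavidin beads. The material was 2-week-old seedlings of the rice cultivar Nipponbare, cross-linked with 1% formaldehyde for 10 min. The 10 libraries fell into 7 groups. BioCyTASQ in vitro, BioTASQ in vitro and BioTASQ in vivo had 2 libraries each, and biotin alone and input had 1 library each for the in vitro and the in vivo set. The labels say only vitro or vivo, and none of the 10 libraries was labelled as BG4.

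The measurements were 4 lists of capture peaks, 1 list per capture and none per replicate, so no value had an error between replicates. In its place the spread over the 12 chromosomes is given, which measures how evenly a result held along the genome and not how it would vary between seedlings. Coordinates are counted from 1 on the rice build of the deposited lists, which is not given in the sources used here, and which genes lie at them was not analysed here. Fold enrichment is the authors' value of a peak over its control. Read depths were not analysed here. All tests over chromosomes were exact two-sided sign-flip permutation tests, whose smallest possible p with 12 chromosomes is 0.000488.

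BioTASQ in vivo had the most peaks, 57500, which covered 24.7 Mb. BioCyTASQ in vitro had 49898 peaks, and they covered more of the genome, 27.3 Mb. The list named for BioTASQ in vitro had 29443 distinct peaks over 8.16 Mb. Median peak width was 413 bp for BioCyTASQ in vitro, 342 bp for BioTASQ in vivo and 228 bp for the list named for BioTASQ in vitro. Peaks lay on all 12 chromosomes at 135 ± 10.1 per Mb for BioCyTASQ in vitro, 154 ± 6.59 for BioTASQ in vivo and 79.4 ± 3.81 for the list named for BioTASQ in vitro (mean ± SD, n = 12 chromosomes). The lists were not made to one threshold. The lowest −log10 q in the authors' deposited table was 1.31 for BioCyTASQ in vitro, against 3.01 for BioTASQ in vivo and 3.0 for the list named for BioTASQ in vitro. At a −log10 q of at least 3, 48005 BioCyTASQ peaks were left.

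The comparison in the series title, antibody against small molecule, could not be made from these lists. The list deposited for BG4 and the list deposited for BioTASQ in vitro held the same 29469 rows, and 0 rows differed. Which of the captures these peaks come from cannot be read from the rows with certainty. Below they are called the BG4/BioTASQ in vitro list. BioTASQ and BioCyTASQ, related baits under the same in vitro label, could for the same reason not be compared with certainty.

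BioCyTASQ in vitro and the BG4/BioTASQ in vitro list shared a minority of their peaks, and more than chance placement gave. Of the BioCyTASQ peaks, 11589 or 23.2% (SD 2.0, n = 12 chromosomes) touched a BG4/BioTASQ in vitro peak by at least 1 bp, against 6.25% after shuffling, a 3.72-fold excess. In the other direction 42.1% (SD 4.45) of the BG4/BioTASQ in vitro peaks lay on a BioCyTASQ peak, 3.85 times the shuffled 10.9%. The excess was present on 12 of 12 chromosomes in both directions (p = 0.000488, exact, and 0.000488 after Benjamini-Hochberg adjustment over 6 overlaps).

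The strongest regions that BioCyTASQ in vitro shared with the BG4/BioTASQ in vitro list lay on chromosomes 7, 10 and 12. On chromosome 7, the BioCyTASQ peak at 23448252 to 23450348 had a fold enrichment of 10.0, and the overlapping peak at 23450128 to 23450544 had 11.3. On chromosome 10, the peaks at 20422637 to 20424224 and 20422475 to 20422743 had 10.6 and 9.94. On chromosome 12, those at 12790191 to 12790762 and 12790727 to 12791663 had 9.07 and 10.0. These 3 regions also held a BioTASQ in vivo peak. The strongest BioCyTASQ peaks outside the BG4/BioTASQ in vitro list had fold enrichments of 20.8 on chromosome 8 (8697799 to 8699320), 19.0 on chromosome 4 (5278189 to 5280856) and 18.1 on chromosome 6 (4452126 to 4452898). They were picked by BioCyTASQ fold alone and the shared regions by rank in both lists, so the values are not set against each other. All 3 were BioTASQ in vivo peaks as well. The strongest BG4/BioTASQ in vitro peaks outside the BioCyTASQ list had 21.1 on chromosome 4 (942545 to 942879), 19.4 on chromosome 1 (19404937 to 19405249) and 19.4 on chromosome 1 (9638113 to 9638903). None of these 3 was a BioTASQ in vivo peak.

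Strong BioCyTASQ peaks, ranked by fold enrichment, were in the BG4/BioTASQ in vitro list less often than weak ones. The overlap was 31.1% (SD 2.02) for the weakest 9980 peaks and 10.1% (SD 1.45) for the strongest group of the same size, a mean fall of 20.9 percentage points (SD 1.72, lower on 12 of 12 chromosomes, p = 0.000488, exact). BG4/BioTASQ in vitro peaks showed the same direction, from 48.1% of the weakest to 34.7% of the strongest on a BioCyTASQ peak, but at 50% reciprocal overlap the change was 1.68 points upward (p = 0.00439, exact). The direction for BioCyTASQ depended on the measure of strength: ranked by −log10 q it was 19.96% for the weakest and 22.8% for the strongest, and ranked by the recovered pileup, the number of fragments at the summit, 11.8% and 43.5%. Ranked by the recovered control level, the fragment number expected from the control, the share of BioCyTASQ peaks in the BG4/BioTASQ in vitro list was 5.23% at the lowest and 58.2% at the highest levels, and their share in the BioTASQ in vivo list 36.2% and 87.6%. The fall with fold enrichment was −12.6 points at 50% reciprocal overlap and −8.99 points with the stronger peaks of each list alone. Across 12518 overlapping pairs, the fold enrichments of BioCyTASQ in vitro and BG4/BioTASQ in vitro peaks were not detectably related (Spearman rho −0.018, p = 0.242, exact, on its values per chromosome). The share of BioCyTASQ peaks in the BG4/BioTASQ in vitro list was 6.50% at 50% reciprocal overlap, 15.0% with 200 bp windows at the summits and 8.43% with the stronger peaks of each list alone, and its excess over shuffled placement ran from 2.22-fold to 5.60-fold. Which control library each list was called against is not given in the sources used here, so part of any overlap may come from a shared control.

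BioTASQ in vivo and the BG4/BioTASQ in vitro list, the comparison of conditions for BioTASQ if the list is that of BioTASQ, also shared more peaks than chance placement gave. Of the in vivo peaks, 10424 or 18.1% (SD 1.81, n = 12 chromosomes) lay on a BG4/BioTASQ in vitro peak, 3.35 times the shuffled 5.41%. Of the BG4/BioTASQ in vitro peaks, 36.6% (SD 1.78) lay on an in vivo peak, 3.40 times the shuffled 10.8%. The excess held on 12 of 12 chromosomes (p = 0.000488, exact, in both directions). At 50% reciprocal overlap the share of in vivo peaks was 5.73%, and with 200 bp windows 11.4%. Whether it lay below or above the 23.2% of BioCyTASQ peaks in the same list depended on the setting: with equal numbers of the strongest peaks 21.6% of in vivo and 19.1% of BioCyTASQ peaks were in it, and with the stronger peaks of each list alone 12.3% and 8.43%.

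The strongest regions shared by BioTASQ in vivo and the BG4/BioTASQ in vitro list lay on chromosomes 4 and 10. The in vivo peak on chromosome 4 at 34098913 to 34099267 had a fold enrichment of 7.93 beside 18.9 for the overlapping peak at 34098760 to 34099186. On chromosome 10, the in vivo peak at 1677139 to 1677678 had 8.02 beside 13.6 (1677292 to 1677837), and the in vivo peak at 16464881 to 16465584 had 10.2 beside 11.2 (16465347 to 16465517). BioCyTASQ in vitro had a peak at all 3. The strongest in vivo peaks outside the BG4/BioTASQ in vitro list had fold enrichments of 16.01 on chromosome 8 (6944835 to 6945107), 12.7 on chromosome 7 (27299779 to 27300355) and 12.1 on chromosome 4 (11983463 to 11983786), and BioCyTASQ in vitro had a peak at all 3. The strongest BG4/BioTASQ in vitro peaks outside the in vivo list were the same 3, on chromosomes 1 and 4, that lay outside the BioCyTASQ list.

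Strong BioTASQ in vivo peaks were in the BG4/BioTASQ in vitro list more often than weak ones, 23.7% (SD 3.48) of the strongest 11500 against 12.8% (SD 0.965) of the weakest by fold enrichment. The mean rise was 11.4 percentage points (SD 3.17, on 12 of 12 chromosomes, p = 0.000488, exact). The rise was 1.26 points at 50% reciprocal overlap, 1.30 with 200 bp windows at the summits, 2.16 with the stronger peaks of each list alone and 6.45 with equal numbers of the strongest peaks. With 200 bp windows at the centre of the rows it was 1.40 points (p = 0.0566, exact), no longer past the threshold of 0.05. BG4/BioTASQ in vitro peaks were on an in vivo peak in 34.5% of the weakest and 46.6% of the strongest group, a mean rise of 12.4 points that ran from 4.06 with 200 bp windows to 19.9 when ranked by −log10 q. Fold enrichments of 10935 overlapping pairs ran weakly against each other (rho −0.051, negative on 12 of 12 chromosomes, p = 0.000488, exact, adjusted p = 0.000732 over 6 correlations).

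**Figure D1:**
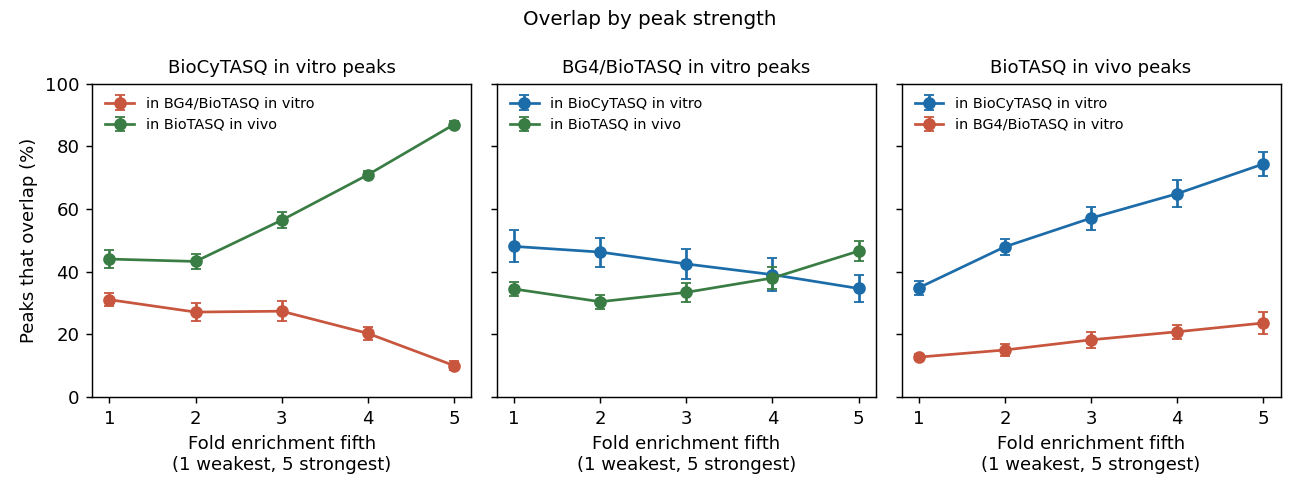
Percent of peaks that overlap a peak of another list by at least 1 bp, for 5 equal groups of peaks from the weakest to the strongest fold enrichment, with 1 panel per list. Points are genome-wide shares and error bars the SD over 12 chromosomes. From the weakest to the strongest group, BioCyTASQ in vitro peaks went from 31.1% to 10.1% in the BG4/BioTASQ in vitro list and from 44.05% to 86.9% in the BioTASQ in vivo list.

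BioCyTASQ in vitro and BioTASQ in vivo, which differ in both bait and condition, had the most peaks in common. This comparison was added after the data were examined. Rows of both lists had been cut after calling, with no sign of it in the BG4/BioTASQ in vitro list. Like processing therefore cannot be told apart from like capture. Of the BioCyTASQ peaks, 30102 or 60.3% (SD 2.13, n = 12 chromosomes) lay on an in vivo peak, 4.23 times the shuffled 14.3%. Of the in vivo peaks, 55.9% (SD 2.56) lay on a BioCyTASQ peak, 4.41 times the shuffled 12.7% (12 of 12 chromosomes in both directions, p = 0.000488, exact). Among the strongest BioCyTASQ peaks by fold enrichment 86.9% (SD 1.09) were in vivo peaks, against 44.05% (SD 2.91) of the weakest. Fold enrichments of 32614 overlapping pairs rose together (rho 0.243, positive on 12 of 12 chromosomes, p = 0.000488, exact, adjusted p = 0.000732).

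The strongest regions shared by BioCyTASQ in vitro and BioTASQ in vivo were at chromosome 4, 13636223 to 13639481, with a BioCyTASQ fold enrichment of 15.9, at chromosome 1, 27451499 to 27452643, with 14.1, and at chromosome 2, 3010823 to 3014372, with 15.3. The in vivo peaks inside them had 8.22, 9.44 and 8.12. None of the 3 was in the BG4/BioTASQ in vitro list. BioCyTASQ peaks outside the in vivo list reached 15.2 on chromosome 1 (33019642 to 33019868), 13.5 on chromosome 5 (10193026 to 10193948) and 13.4 on chromosome 6 (22458257 to 22458638), and of these the chromosome 5 region was in the BG4/BioTASQ in vitro list. In vivo peaks outside the BioCyTASQ list reached 11.3 on chromosome 11 (5028143 to 5028668), 10.3 on chromosome 4 (35499451 to 35501119) and 9.84 on chromosome 4 (3250266 to 3250893), and both chromosome 4 regions were in the BG4/BioTASQ in vitro list.

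Relative to chance, BioCyTASQ in vitro peaks overlapped the BioTASQ in vivo list more than the BG4/BioTASQ in vitro list. The log2 ratio of the 2 excesses was 0.18 (SD 0.12, positive on 11 of 12 chromosomes, p = 0.000977, exact, adjusted p = 0.000977 over 3 comparisons). In vivo peaks likewise overlapped BioCyTASQ more than the BG4/BioTASQ in vitro list, by 0.39 (SD 0.11, 12 of 12 chromosomes, p = 0.000488, exact, adjusted p = 0.000732). BG4/BioTASQ in vitro peaks overlapped the in vivo list less than the BioCyTASQ list (log2 ratio −0.18, SD 0.05, negative on 12 of 12 chromosomes, p = 0.000488, exact, adjusted p = 0.000732), but more than it with equal numbers of the strongest peaks (0.27) or with the stronger peaks of each list alone (0.69). These comparisons were added after the data were examined. The BioCyTASQ ratio kept its sign and depended on the setting: 0.48 when at least 50% of the shorter peak had to overlap, 1.18 at 50% reciprocal overlap, 0.71 with 200 bp windows, 1.0 with equal numbers of the strongest peaks and 1.39 with the stronger peaks of each list alone. The in vivo ratio kept its sign as well and ran from 0.37 to 1.39. Rows of the BioCyTASQ and in vivo lists had been cut after calling, with no sign of it in the BG4/BioTASQ in vitro list. These ratios therefore cannot separate like capture from like processing.

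**Figure D2:**
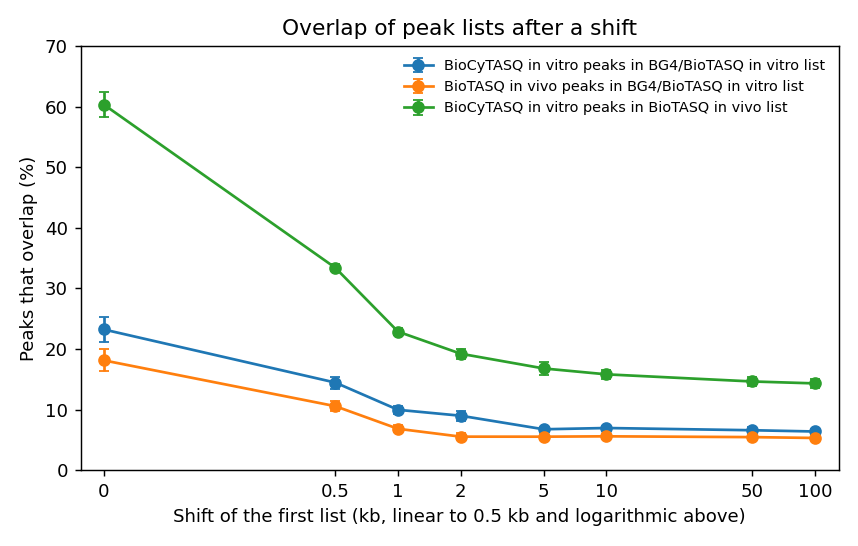
Percent of peaks of the first list that overlap the second by at least 1 bp after the first was moved along the chromosome by 0 to 100 kb (horizontal axis linear to 0.5 kb and logarithmic above). Points are genome-wide shares and error bars the SD over 12 chromosomes; a shift of 0.5 kb lowered BioCyTASQ in vitro overlap with BioTASQ in vivo from 60.3% to 33.4%, and at 5 kb it was 16.8%.

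Most of each overlap was local, a check also added after the data were examined. Moving the BioCyTASQ peaks by 0.5 kb lowered their share in the BG4/BioTASQ in vitro list from 23.2% to 14.5% (SD 0.998), and at 5 kb the share was 6.76% (SD 0.412), near the shuffled 6.25%. The in vivo peaks went from 18.1% to 10.6% at 0.5 kb and 5.54% at 5 kb in the same list, near the shuffled 5.41%. The share of BioCyTASQ peaks in the in vivo list was still above the shuffled 14.3% at 5 kb, at 16.8% (SD 1.10), and at 10 kb, at 15.8% (SD 0.755), and was 14.6% at 50 kb.

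Merging the 3 distinct lists gave 87915 regions, of which 7976 or 9.07% held a peak of every list. Regions of BioCyTASQ in vitro and BioTASQ in vivo without the BG4/BioTASQ in vitro list were the most frequent shared kind, 21617 or 24.6%. BioCyTASQ with BG4/BioTASQ in vitro alone made up 3913 regions (4.45%), and BioTASQ in vivo with BG4/BioTASQ in vitro alone 3170 (3.61%). BioTASQ in vivo alone held 22134 regions, BioCyTASQ in vitro alone 15797 and the BG4/BioTASQ in vitro list alone 13308. Of the BG4/BioTASQ in vitro peaks, 7043 or 23.9% (SD 2.55, n = 12 chromosomes) lay on peaks of both other lists, 4.07 times the shuffled 5.88% (12 of 12 chromosomes, p = 0.000488, exact). That share was 4.02% at 50% reciprocal overlap, 8.65% with the stronger peaks of each list alone, 11.01% with 200 bp windows and 11.1% with equal numbers of the strongest peaks.

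A BG4/BioTASQ in vitro peak lay on a BioCyTASQ peak in 65.4% (SD 4.10) of cases where it also lay on an in vivo peak, and in 28.7% (SD 3.87) where it did not (12 of 12 chromosomes, p = 0.000488, exact). BioCyTASQ peaks were in the BG4/BioTASQ in vitro list in 25.2% inside and 20.2% outside the in vivo list. In vivo peaks were in it in 22.3% inside and 12.8% outside the BioCyTASQ list. Both differences were positive on 12 of 12 chromosomes (p = 0.000488, exact, also after adjustment over the 3 comparisons, which were added after the data were examined). The partner lists overlapped each other, so chance placement also makes a peak on the first lie on the second more often. Of the shuffled BG4/BioTASQ in vitro peaks, 10.8% lay on an in vivo peak, 10.9% on a BioCyTASQ peak and 5.88% on both. These tests against no difference therefore show no link beyond the pairwise overlaps.

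**Figure D3:**
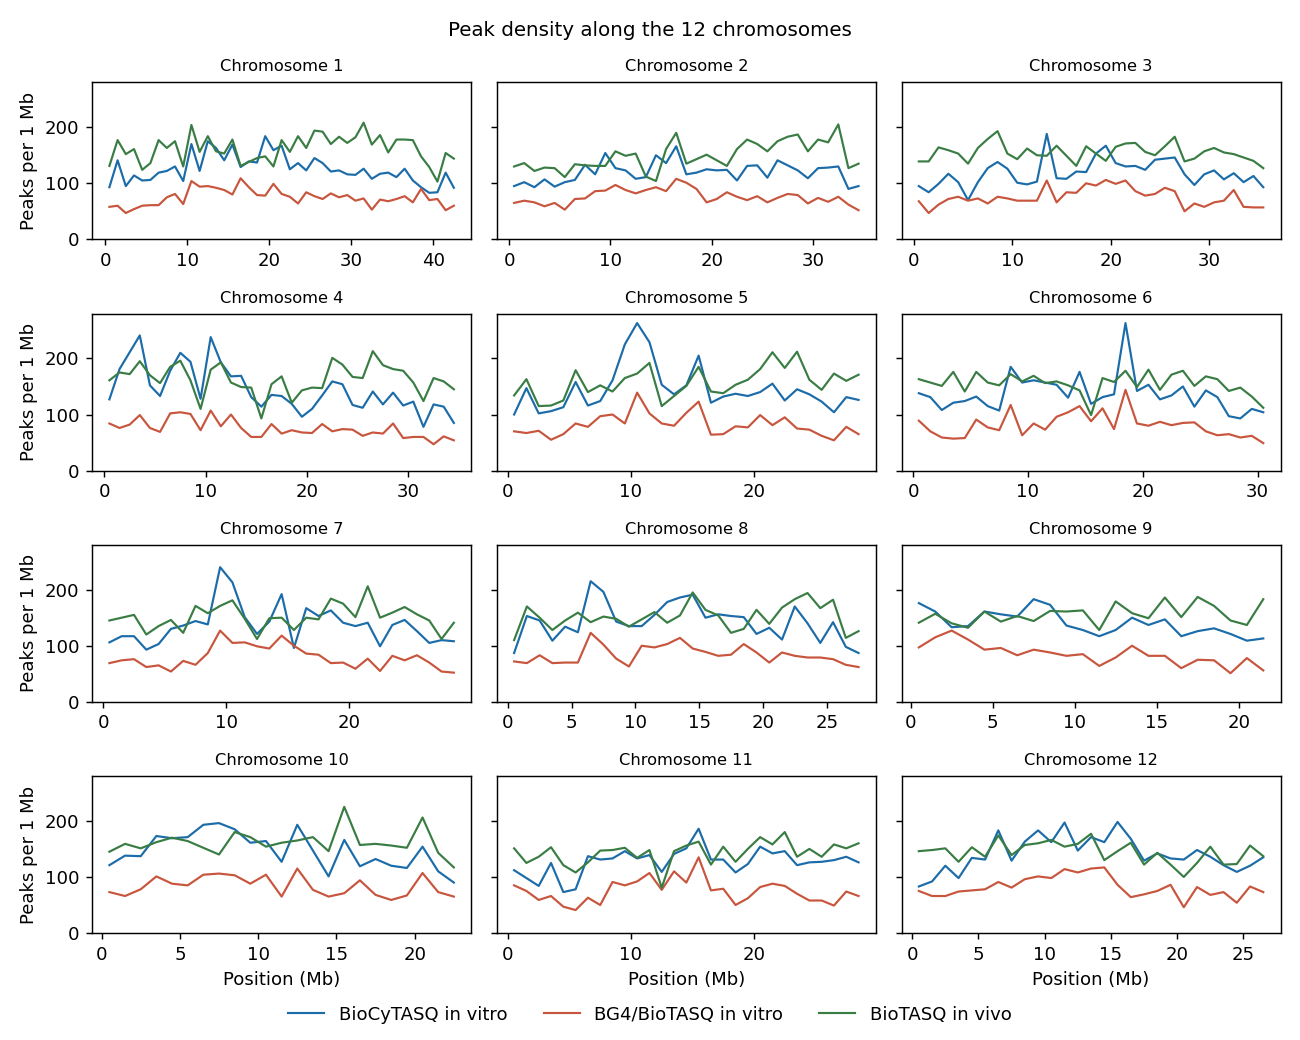
Peaks per 1 Mb (vertical axis) along each of the 12 chromosomes (horizontal axis, position in Mb) for the BioCyTASQ in vitro, BG4/BioTASQ in vitro and BioTASQ in vivo lists. BioCyTASQ reached 263 peaks in single 1 Mb stretches of chromosomes 5 and 6, against a median of 131, and the BG4/BioTASQ in vitro list reached 139 and 144 in the same stretches, against a median of 76.

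Along the chromosomes, BioCyTASQ in vitro and the BG4/BioTASQ in vitro list were dense in the same stretches, a description added after the data were examined. Both had their densest 1 Mb stretches on chromosome 5 (10000001 to 11000000) and chromosome 6 (18000001 to 19000000), with 263 BioCyTASQ peaks in each and 139 and 144 BG4/BioTASQ in vitro peaks. BioTASQ in vivo was densest on chromosome 10 (15000001 to 16000000), with 225 peaks against a median of 154. Across 367 stretches of 1 Mb, peak numbers were correlated with Spearman rho 0.651 for BioCyTASQ and BG4/BioTASQ in vitro, 0.434 for BioCyTASQ and BioTASQ in vivo, and 0.223 for BioTASQ in vivo and BG4/BioTASQ in vitro. Within single chromosomes rho ran from 0.556 to 0.793 for the first pair, from −0.039 to 0.629 for the second and from −0.292 to 0.451 for the third. Stretches are not replicates. A permutation test that rotated 1 list along each chromosome 1000 times gave p = 0.001, 0.001 and 0.002.

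In the outer 5 Mb of the chromosome arms, peaks of every list were sparser than further in. BioCyTASQ in vitro had 116 peaks per Mb there and 144 in the interior (log2 ratio −0.31, SD 0.14, lower on 12 of 12 chromosomes, p = 0.000488, exact, adjusted p = 0.000977 over 3 lists). The BG4/BioTASQ in vitro list had 69.98 and 83.9 (log2 ratio −0.26, SD 0.14, lower on 11 of 12, p = 0.000977, exact). BioTASQ in vivo had 147 and 157 (log2 ratio −0.10, SD 0.08, lower on 11 of 12, p = 0.000977, exact). The in vivo ratio was higher than that of BioCyTASQ by 0.21 (SD 0.12, 12 of 12 chromosomes, adjusted p = 0.00146, exact) and than that of BG4/BioTASQ in vitro by 0.17 (SD 0.13, 11 of 12, adjusted p = 0.00366, exact), while the in vitro lists did not differ detectably (0.04, SD 0.10, p = 0.165, exact). The in vivo deficit was not past the threshold with the stronger peaks alone (−0.04, p = 0.305, exact) or with equal numbers of the strongest peaks (−0.05, p = 0.262, exact), and the BioCyTASQ deficit was −0.17 and −0.20 there.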

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

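All tests in this part were chosen after the result was seen, and control level, first counted as an explanation that the values bore out, was narrowed to the whole cause after its result was seen.

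BioCyTASQ in vitro peaks behaved in opposite ways toward the other lists as fold enrichment rose. The change in overlap from the weakest to the strongest group was 63.9 percentage points higher toward BioTASQ in vivo than toward the BG4/BioTASQ in vitro list (SD 2.91, on 12 of 12 chromosomes, p = 0.000488, exact sign-flip permutation test). Overlap with BioTASQ in vivo rose by 42.9 points, while overlap with the BG4/BioTASQ in vitro list fell by 20.9 points. The opposite directions held for fold enrichment alone: ranked by −log10 q both overlaps rose, by 62.6 and 2.95 points, and ranked by pileup, the fragment number at the summit, by 75.1 and 31.7 points.

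For the fall toward the BG4/BioTASQ in vitro list, the tables argue against peak width, since the change was −23.6 points with 200 bp windows, and against the looser q threshold of the BioCyTASQ list, since it was −22.2 points once every peak had a −log10 q of at least 3. Within groups of like control level, the fragment number the peak caller expected at a peak, the change averaged −5.95 points (SD 2.0, negative on 12 of 12 chromosomes, p = 0.000488, exact). Over all peaks it was −20.9, so level went with part of the fall. Levels still varied within a group, so the remainder does not exclude level as the whole cause. BioCyTASQ fold enrichment and control level were correlated (Spearman rho −0.217 across peaks, negative on 12 of 12 chromosomes), partly because the level divides the fold. In the 3 groups with the lowest levels the weakest peaks overlapped 3.06, 3.88 and 2.50 times as often as the strongest, against 3.08 times over all BioCyTASQ peaks, while the ratio was 1.32 and 0.96 in the 2 groups with the highest levels. In the 2 lowest groups the shares were small, 5.06% against 1.65% and 10.9% against 2.81%. Shuffled placement gave 6.25% over all peaks. From the lowest to the highest level the changes were −3.50, −7.97, −11.9, −8.42 and 2.08 points (p = 0.345, exact, for the last). What the fall within groups of like level comes from stays open, and a difference between baits or between BG4 and a bait was not tested.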

How the results depend on the processing

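Across 16 results and 334 alternatives, 327 kept their direction and their side of the threshold. Of the alternatives, 19 moved no peak of the lists compared and show nothing about stability, among them all 13 mergings within 100 bp, which joined 0 peaks, and 5 of the −log10 q of at least 3. Leaving out a chromosome could hardly turn a result that held on all 12 chromosomes, so those alternatives show little about stability either. None of the 7 that changed came from leaving out a chromosome. Of the 315 outside those 19, 308 kept their direction and their side of the threshold. Each overlap did so under all of its alternatives: BioCyTASQ in the BG4/BioTASQ in vitro list at 6.50% to 23.5%, BioTASQ in vivo in that list at 5.73% to 21.6%, BioCyTASQ in BioTASQ in vivo at 40.8% to 61.3%, and BG4/BioTASQ in vitro peaks in both others at 4.02% to 24.4%. The log2 ratio between the BioCyTASQ overlaps ran from 0.17 to 1.39. That of the BG4/BioTASQ in vitro overlaps, BioTASQ in vivo over BioCyTASQ, was reversed with the stronger peaks of each list (0.69) and with equal numbers of the strongest peaks (0.27). Ranked by −log10 q, which was chosen after seeing the data, the change in BioCyTASQ overlap with the BG4/BioTASQ in vitro list from weakest to strongest was reversed, at 2.95 points. At 50% reciprocal overlap the change in BG4/BioTASQ in vitro overlap with BioCyTASQ was reversed, at 1.68 points. The rise of BioTASQ in vivo overlap with the BG4/BioTASQ in vitro list was 1.40 points with 200 bp windows at row centres (p = 0.0566, exact), and the in vivo deficit at chromosome ends was −0.046 with equal numbers of peaks and −0.042 with the stronger peaks, both on the log2 scale. For these 7 the cause was not tested. No paired analysis was possible because each capture group has 1 list and none per replicate, and for the same reason no replicate was left out. Alternatives for motifs, annotation, base composition and gene lists were not run, since no genome of the build was used here, and those for the BG4 overlap were not run because the lists are the same. Depth may limit which peaks near the thresholds were called. This was not tested, and depth was not analysed per library.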

Other observations

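All tests in this part were chosen after the result was seen. Coverage in every library, peak width and regional peak density were narrowed to the whole cause after their results were seen.

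The regions with the highest −log10 q were high-coverage loci in the in vitro lists. The highest BioCyTASQ peak in the authors' deposited table lay on chromosome 6 at 56078 to 56604, with a −log10 q of 3729, and the overlapping peak at 56141 to 56546 was the highest of the BG4/BioTASQ in vitro list, at 514. Its BioCyTASQ fold enrichment was 5.70, with a control level of 1643 fragments, and BioTASQ in vivo had no peak there. Of the 10 highest BioCyTASQ peaks, 10 were in the BG4/BioTASQ in vitro list and 1 was in the BioTASQ in vivo list, and their median control level was 51.2 times the lowest of the list. The 10 highest BioTASQ in vivo rows were pieces of 8 called peaks. Of the 10 highest called peaks, with pieces of the same name counted once, 10 were in the BioCyTASQ list and 6 in the BG4/BioTASQ in vitro list, at a median control level 1.69 times the lowest. The in vivo peak on chromosome 8 at 6944835 to 6945107 had both the highest fold enrichment of its list, 16.01, and the second-highest −log10 q in the authors' deposited table, 300.1.

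The same list was deposited for BG4 and for BioTASQ in vitro. Separate experiments could not be tested, since the 0 rows that differ only restate that the lists are the same. The tables argue against a list made by the same steps as the others, since 0% of its rows had a summit beyond the row end, against 2.01% for BioCyTASQ in vitro and 22.97% for BioTASQ in vivo. In 100% of its peak names the word flag appeared, and neither TASQ nor biotin did. BG4 is commonly used with a FLAG tag, so a candidate explanation is that the list is that of BG4 and was deposited under both names. Only the peak names point to BG4. The uncut rows, and whole pileups in 0.333% of its peaks against 100% in both other lists, set the list apart. They do not show which capture it holds, and no biological explanation was tested.

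BioCyTASQ peaks at a high control level were found most often in the BG4/BioTASQ in vitro list, from 5.23% at the lowest level to 58.2% at the highest, a rise of 52.97 points (SD 1.99), and in the BioTASQ in vivo list, by 51.6 points (SD 4.51, both on 12 of 12 chromosomes, p = 0.000488, exact), so the rise was not particular to the former. Toward the BG4/BioTASQ in vitro list it was 37.9 points with 200 bp windows, which argues against peak width, and 4.30 points after a shift of 5 kb, which argues against regional peak density. Whether loci with high coverage in every library are the whole cause was not decided. BG4/BioTASQ in vitro peaks ranked by their own level changed by −2.37 points in overlap with BioCyTASQ (SD 4.90, p = 0.122, exact). The absent trend goes against the explanation. That level is approximate, since only 0.333% of these peaks gave a whole pileup, which limits any trend with it. By the same approximate level, BG4/BioTASQ in vitro peaks rose by 19.3 points toward BioTASQ in vivo (SD 4.37, on 12 of 12 chromosomes), so approximation alone need not account for the absent trend. This rise goes with the explanation. BioCyTASQ and BG4/BioTASQ in vitro levels of overlapping pairs were also correlated (rho 0.283). In vivo peaks went the other way with their own level, from 67.4% to 39.9% on BioCyTASQ peaks. The mean change was −27.8 points (SD 2.20, on 12 of 12 chromosomes, p = 0.000488, exact), and 0.31 points toward BG4/BioTASQ in vitro (p = 0.604, exact). In vivo levels were little correlated with the other lists (rho 0.063 with BioCyTASQ and −0.018 with BG4/BioTASQ in vitro). They spanned little, since 41.4% lay at the lowest value and 0.172% reached 2 times it. That the control of BioCyTASQ itself held captured or G-quadruplex-rich fragments may account for the rise, and stays open because the control libraries were not analysed here.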
